A study of Mus musculus with 24 samples.

How the data were processed

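RNA of mouse livers was measured by sequencing in 24 libraries, 6 for each of 4 gavage groups. Per the labels' protocols, livers of male C57BL/6 mice weighing 20 to 30 g were frozen in liquid nitrogen, RNA was taken up in Trizol, and libraries were made from 1 ug of total RNA with an Illumina TruSeq kit. The labels give no duration of treatment, no time of collection, no batch and no statement on pooling, and they describe 12 mice per group for 6 libraries. Each library was assigned to its group and replicate number from its title.

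The authors deposited a table for each library with an NCBI gene identifier, a symbol, an expected count and an FPKM value for every gene above 0. Expected counts are estimated reads per gene without normalisation, per the file headers, and between 94.5% and 95.3% of them were whole numbers in the deposited tables. The deposited FPKM values are those counts per kilobase of transcript and scaled to the library's assigned reads, per the file headers and as a check of the values against the counts showed. The submitters' processing notes name Cuffdiff, with no version or role, and the genome builds mm10 and GRCm38. The aligner, the program that estimated the counts, its treatment of reads shared between similar genes, its filters and its use of strand are not given in the sources used here. Genes encoded by the mitochondrial genome were not analysed here. In total 17537 genes appeared in at least 1 table. Of their identifiers, 17491 were placed in the RefSeq gene table of GRCm38.p6, from which the coordinates come, and 46 were not. A symbol was missing for 7.

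Total expected counts ranged from 7324793 to 8016662 per library. The depth limits what can be said of weakly expressed genes, so a gene was tested when it reached 1 FPKM in at least 6 of the 24 libraries, which left 10697 genes. Expected counts were rounded to whole numbers and tested in edgeR 4.0.16 (R 4.3.3) with TMM factors, a negative binomial model with all 4 groups and no further covariate, and the quasi-likelihood F test, with 20 residual degrees of freedom. The p-values of each comparison were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p below 0.05. Log2 changes are model estimates as edgeR reports them, slightly shrunken by its default prior count. Their standard errors were taken as the absolute unshrunken change divided by the square root of the F statistic. Means and SDs of single genes are in FPKM over 6 libraries. The interaction is the log2 change from DEHP to the combination minus that from vehicle to ethanol.

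The plan had assumed that the tables held FPKM alone and named limma on log2(FPKM + 1) as the test. Since they also held expected counts, the count test became the main test, and limma 3.58.1 on log2(FPKM + 1) was kept as an alternative. The comparisons, the filter, the threshold, the gene lists, the rule for named genes and the alternatives listed as planned were chosen before the data were examined. Under that rule, the text names in each comparison the 8 largest rises and the 8 largest falls in log2(FPKM + 1) among called genes with a mean of at least 1 FPKM in a compared group. It also names up to 4 members with the smallest adjusted p of each list that passed or had at least 25% and at least 3 of its members called, and 18 fixed genes, of which 17 were tested and some are not reported here. Genes with a predicted-gene name were passed over. Where only some of these genes are given, they were picked among those that the rule names. Given outside the rule are Arntl, Cry1, Cry2 and Nfil3 for ethanol against vehicle and Fabp4 for DEHP against vehicle. Acta1, Ctrb1, Amy2a5 and the other muscle genes were added after their values were seen. The other pancreas genes come from a test written down before it was run, but for a library already picked out for pancreatic transcripts.

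Of 43 gene lists fixed beforehand, 10 of them markers of cell types, the 37 with at least 5 tested members were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. It was repeated with a correlation estimated for each list, and fry was run as a test of each list by itself. Adjusted p-values cover the 37 lists of a comparison. Counts adjusted over the list alone apply the Benjamini-Hochberg method to the members of that list. Principal components were computed on log2 counts of the tested genes, scaled by library size and TMM factors.

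The test was tried on simulated counts of all 4 groups, drawn from the means of the vehicle libraries, with changes put into the ethanol group. With 10697 genes tested and known changes of 1.5, 2 and 4-fold in 67, 67 and 66 genes, edgeR recovered 73.1%, 86.6% and 100% with the right sign, and 5.6% of its calls were unchanged genes. With no gene changed, in a simulation of the DEHP and vehicle comparison, it called 0. In the simulated ethanol comparison camera gave an adjusted p of 1.02e-22 for a list of 25 raised genes and called 0 of 20 unchanged lists. Genes were drawn independently of each other there, so the simulation cannot show how often camera calls unchanged lists whose members are correlated.

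Libraries of the same group were compared for duplicates. Over 60 pairs, chi-square per degree of freedom was 6.65 to 63.64, with a median of 19.84, so that no pair agreed within sampling noise and every library was counted as a sample. Replicate numbers recur in all groups, but nothing in the labels ties a number to an animal, litter or day.

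Alternatives covered low-value filters (none, or 5 FPKM), pseudocounts of 0.1 and 5 for the log2 values, scaling by TPM, by median-ratio size factors or by quantiles, fits of only the groups compared, sample weights, other variance moderation, the replicate number as a block, a further threshold of 2-fold, and each library left out in turn. The planned limma on log2(FPKM + 1) became an alternative once the tables were seen to hold counts. Added after the data were seen were DESeq2 1.42.0, robust moderation in edgeR, edgeR with median-ratio factors or with library size only, the omission of the 3 libraries with transcripts of other tissues, and the removal of each library's trend of expression with gene length. Overlaps between comparisons against vehicle were set beside simulations of unchanged groups and beside fits with the vehicle libraries divided between the comparisons. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.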

Results

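Gene expression was measured by RNA sequencing in the livers of male C57BL/6 mice after gavage. Of the 4 groups, one received the vehicle, 0.5% CMC, one ethanol at 1 g/kg body weight, one di(2-ethylhexyl) phthalate (DEHP), a plasticiser that acts as a peroxisome proliferator in rodent liver, at 2500 mg/kg, and one both at the same doses. The titles name CMC for the vehicle group alone, and whether the other groups also received it is not stated there. If they did not, treatment and carrier cannot be told apart in the comparisons against vehicle. Each group was represented by 6 libraries, 24 in all, while the labels describe 12 mice per group. Total expected counts in replicates 1 to 6 were 7538356, 7584522, 7590614, 7580950, 7679886 and 7510462 with vehicle. With ethanol they were 7903506, 7904020, 7912089, 7710151, 7668152 and 7786055. With DEHP they were 7723529, 7607839, 7549895, 7728446, 7324793 and 7779687, and with the combination 7794193, 7882354, 7819936, 7833017, 8016662 and 7564215. Each library listed between 13958 and 15114 genes above 0, and 10697 genes were tested. Because nothing in the labels ties a library to an animal, p-values measure the spread between these samples, which may be technical in part. The 2 by 2 arrangement allowed each treatment to be compared with vehicle, the combination with each single treatment, and the difference between the ethanol changes with and without DEHP (the interaction) to be tested.

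The first principal component held 30.7% of the variance and separated the 12 libraries with DEHP (3.71 to 35.40) from the vehicle (-25.47 to -20.14) and ethanol libraries (-28.72 to -20.38). The second, with 15%, separated vehicle (10.85 to 37.58) from ethanol (-27.32 to -12.40), with the combination libraries in between (-9.16 to 10.56) and the DEHP libraries (-6.05 to 11.41) above ethanol and overlapping the vehicle range. Single libraries also held transcripts of other tissues. Acta1, skeletal muscle actin, reached 1775 FPKM in vehicle replicate 1 and 1460 FPKM in combination replicate 6, against at most 0.91 FPKM in the remaining libraries. The pancreatic enzymes Ctrb1 and Amy2a5 reached 162 and 128 FPKM in DEHP replicate 6, against at most 0.19 FPKM elsewhere.

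**Figure D1:**
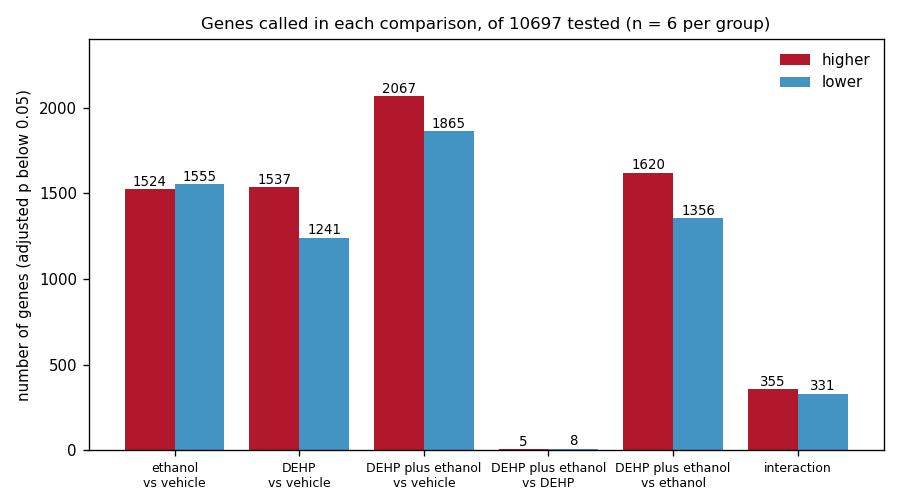
Number of genes called higher (red) or lower (blue) at adjusted p below 0.05 (y axis) in each of the 6 comparisons (x axis), with 6 libraries per group. The combination differed from vehicle in 2067 genes that were higher and 1865 that were lower, and from DEHP alone in 5 and 8.

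Ethanol against vehicle. The clock genes Dbp and Nr1d1 had the largest rises among called genes after ethanol. Dbp, a clock output transcription factor (NCBI gene 13170, chromosome 7, 45705100 to 45710203, GRCm38.p6), rose from 0.82 ± 0.50 to 48.2 ± 25.7 FPKM (SD, n = 6 per group; log2 change 6.06 ± 0.45 SE, adjusted p = 1.05e-09). Nr1d1, which encodes the clock repressor REV-ERBalpha (gene 217166, chromosome 11, 98767932 to 98775377), rose by 3.32 ± 0.34 (adjusted p = 1.5e-07), and Tef, a relative of Dbp, by 1.97 ± 0.17. Cdkn1a, the cyclin-dependent kinase inhibitor p21 (gene 12575, chromosome 17, 29090979 to 29100722), fell from 56.3 ± 14.7 to 1.5 ± 0.46 FPKM (log2 change -5.15 ± 0.21, adjusted p = 4.76e-15). Lpin1, a phosphatidate phosphatase induced by fasting (gene 14245, chromosome 12, 16535669 to 16653903), fell from 72.7 ± 17.1 to 10.1 ± 3.35 FPKM (-2.79 ± 0.21, adjusted p = 1.14e-09).

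Of the 16 clock genes tested, 6 rose, 7 fell and 3 did not pass. Adjusted over the list alone, 7 rose and 7 fell. Nr1d2 (1.62 ± 0.25) and Cry2 (0.83) rose with Dbp, Nr1d1 and Tef, whereas the activators Npas2 (-3.16, from 3.71 ± 0.47 to 0.40 ± 0.26 FPKM) and Arntl (-1.62) and the repressors Cry1 (-1.17) and Nfil3 (-1.22) fell. Because the members moved both ways, the list did not pass camera, which tests for movement in 1 direction (adjusted p = 0.885), and passed the mixed test of fry (adjusted p = 1.48e-10).

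The heat shock and p53 target lists were shifted downward after ethanol. Of 14 heat shock protein genes, 7 fell and none rose (8 fell adjusted over the list alone; camera adjusted p = 0.000225, and adjusted p = 0.707 with an estimated correlation). Examples are Hspa1b (-1.28 ± 0.17) and Hsp90aa1 (-1.06 ± 0.19), both cytosolic chaperones, the first with reads that may be shared with its near-identical copy Hspa1a. Of 12 p53 targets, 5 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.00608, and adjusted p = 0.339 with an estimated correlation), led by Cdkn1a and the stress protein gene Trp53inp1 (-2.30 ± 0.13, adjusted p = 1.56e-12). The NRF2 and glutathione list (8 of 29 rose and none fell, also adjusted over the list alone; camera adjusted p = 0.12) and the endoplasmic reticulum stress list (2 of 24 rose and 7 fell; 2 and 8 adjusted over the list alone; camera adjusted p = 0.147) did not pass. Of 14 endothelial markers, 7 fell (11 adjusted over the list alone; camera adjusted p = 0.0015, and adjusted p = 0.905 with an estimated correlation), among them Bmp2 (-1.11 ± 0.21), Kdr (-0.83 ± 0.23) and Ehd3 (-0.69 ± 0.15).

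Of 16 genes of gluconeogenesis and fasting, 8 fell and 3 rose, with the same counts adjusted over the list alone. G6pc, the last enzyme of glucose production (gene 14377, chromosome 11, 101367716 to 101377903), fell from 207 ± 36.5 to 60.9 ± 17.7 FPKM (-1.70 ± 0.20, adjusted p = 1.17e-06). Igfbp1, a binding protein repressed by insulin, fell by 2.28 ± 0.46 on the log2 scale, and Pck1, which makes phosphoenolpyruvate, by 0.77 ± 0.19. The list passed camera (adjusted p = 0.0445, and adjusted p = 0.905 with an estimated correlation), but not without any of vehicle 2 or 4, ethanol 1, 2 or 4, or DEHP 1, 3 or 5 (adjusted p 0.0509 to 0.0742). The fall of Pdk4, a kinase that limits glucose oxidation, was -2.07 with all libraries and -0.68, no longer called, without vehicle replicate 1, the vehicle library with muscle transcripts. Cyp7a1, the rate-limiting enzyme of bile acid synthesis (gene 13122, chromosome 4, 6265612 to 6275632), rose from 13.4 ± 4.75 to 35.6 ± 18.2 FPKM (1.46 ± 0.36, adjusted p = 0.00389). The list of bile acid genes did not pass (6 rose and 1 fell of 21; 7 and 1 adjusted over the list alone; camera adjusted p = 0.121). Lipid uptake and droplet genes moved both ways, and their list did not pass (5 rose and 8 fell of 25; 6 and 9 adjusted over the list alone; camera adjusted p = 0.885). Lipe, hormone-sensitive lipase, rose by 1.06 ± 0.13, and Angptl4, a lipoprotein lipase inhibitor, fell by 2.05 ± 0.30 on the log2 scale.

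The ribosomal protein, OXPHOS subunit and proteasome lists were shifted upward after ethanol by small amounts. Of 37 ribosomal protein genes, 22 rose (23 adjusted over the list alone), with a median of 0.23 on the log2 scale (camera adjusted p = 2.27e-06, and adjusted p = 0.905 with an estimated correlation), although such genes share sequence with many processed pseudogenes. Of 37 nuclear OXPHOS subunit genes, 11 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00443, and adjusted p = 0.905 with an estimated correlation). Of 31 proteasome genes, 10 rose and 1 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.0445, and adjusted p = 0.905 with an estimated correlation). The proteasome call was lost without any of vehicle 1, 2 or 3, ethanol 1 or 6, DEHP 3, 4 or 5 or combination 5 (adjusted p 0.0509 to 0.106). It was also lost under 14 other settings, the planned limma on log2(FPKM + 1) among them. After removal of the trend with gene length in each library, the medians were 0.10, 0.03 and 0.02, and none of the 3 lists passed. On TPM the medians of the OXPHOS and proteasome lists were -0.02 and -0.01. Of 18 hepatocyte secreted protein genes, 6 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.00518, and adjusted p = 0.905 with an estimated correlation), with a median of 0.24 that was -0.03 under quantile normalisation. Of 21 male-biased genes, 5 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0445, and adjusted p = 0.905 with an estimated correlation). The male-biased call was lost without any of vehicle 2 or 3 or ethanol 1, 2 or 3 (adjusted p 0.0505 to 0.118), and under 4 other settings.

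Of 25 peroxisomal and omega oxidation genes, 4 rose and 1 fell, with the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0889). Ehhadh (0.11 ± 0.21, adjusted p = 0.721), Cyp4a10 (0.50 ± 0.26, adjusted p = 0.153) and Cyp4a14 (0.21 ± 0.37, adjusted p = 0.705) were not called, nor was Adh1, the main alcohol dehydrogenase (-0.02, adjusted p = 0.941). In all, 3079 of 10697 genes passed, 1524 higher and 1555 lower, and 4437 had an unadjusted p below 0.05. The direction depended on scaling, since TPM gave 481 higher and 2764 lower with a shift of -0.15 in the median of all genes, limma on log2(FPKM + 1) gave 1090 and 1780, and edgeR without TMM factors 930 and 2061. Among the 99 named genes that passed, 96 lay beyond the vehicle mean in all 6 ethanol libraries, and Cish, Bbc3 and Cyp1a2 did so in 5 of 6. Of these genes, 49 had no overlap between the groups. Chance gives that for 0.216% of genes not chosen for it, a rate that cannot judge genes chosen because they were called. Of the 37 lists, 9 passed camera, 5 upward and 4 downward, and 0 did so with an estimated correlation.

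DEHP against vehicle. DEHP raised most genes of the peroxisomal and mitochondrial oxidation lists, with median log2 changes of 0.95 and 0.74, and single genes by much more. Cyp4a14, a microsomal omega hydroxylase (gene 13119, chromosome 4, 115486200 to 115496158), rose from 128 ± 95.1 to 3183 ± 628 FPKM (n = 6 per group; 4.59 ± 0.43, adjusted p = 1.62e-08). Ehhadh, a peroxisomal beta-oxidation enzyme (gene 74147, chromosome 16, 21761285 to 21787834), rose from 98.1 ± 23.4 to 2457 ± 803 FPKM (4.63 ± 0.24, adjusted p = 4.15e-13). Serpina12, the adipokine vaspin (gene 68054, chromosome 12, 104028769 to 104044443), fell from 11.5 ± 3.12 to 0.24 ± 0.34 FPKM (-5.61 ± 0.47, adjusted p = 2.46e-09).

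**Figure D2:**
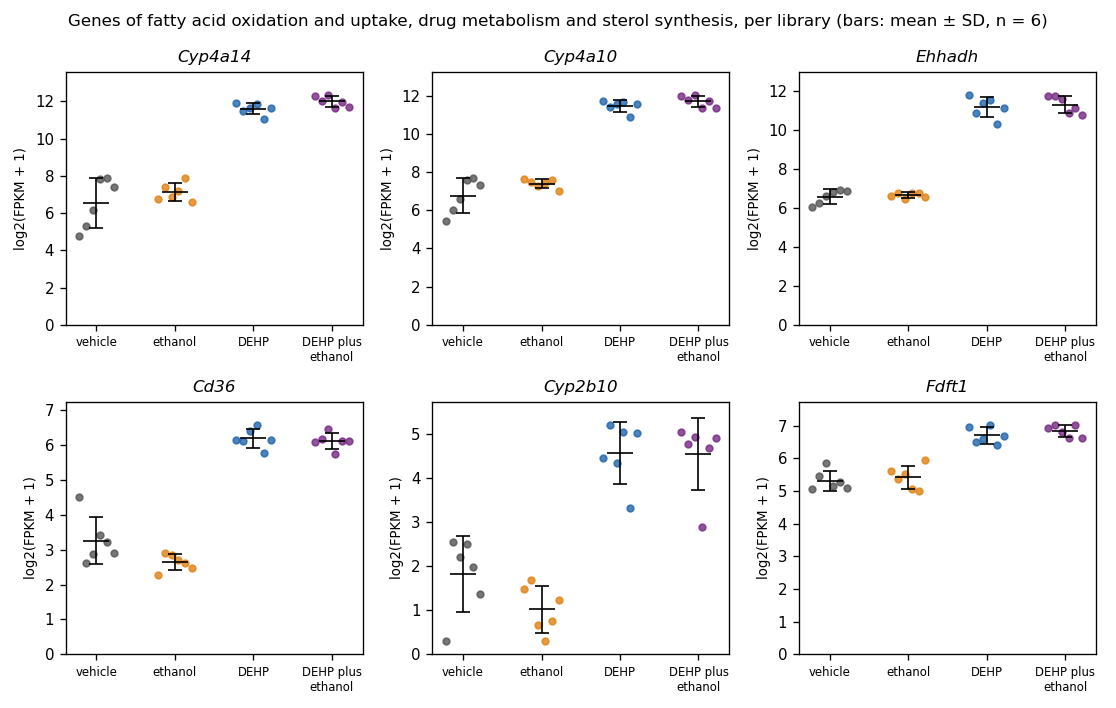
Expression, as log2(FPKM + 1), of Cyp4a14, Cyp4a10, Ehhadh, Cd36, Cyp2b10 and Fdft1 (y axes) in the 4 groups (x axes), with each point a library and bars showing the mean and SD of 6. Cd36 averaged 9.67 FPKM with vehicle, 5.3 with ethanol, 73.6 with DEHP and 69.3 with the combination.

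Of 25 genes of peroxisomal and omega oxidation, 22 rose and none fell (23 and 1 adjusted over the list alone; camera adjusted p = 2.83e-20, and adjusted p = 0.0401 with an estimated correlation). Cyp4a10 (4.51 ± 0.30) was among them, and its reads cannot be separated with certainty from those of its close paralog Cyp4a31 (5.46 ± 0.28). Of 27 genes of mitochondrial oxidation and ketogenesis, 22 rose and none fell, with the same counts adjusted over the list alone (camera adjusted p = 7.58e-21, and adjusted p = 0.0408 with an estimated correlation). Acot2, a mitochondrial acyl-CoA thioesterase, rose by 3.58 ± 0.32, Eci1 by 1.48 ± 0.10 and Decr1, an auxiliary enzyme for unsaturated fatty acids, by 1.31 ± 0.10, whereas Cpt1a, the carnitine step of mitochondrial import (0.15, adjusted p = 0.378), and Cat, peroxisomal catalase (0.22, adjusted p = 0.0581), were not called. Of 25 genes of lipid uptake, binding and droplets, 13 rose and 4 fell (14 and 4 adjusted over the list alone; camera adjusted p = 6.48e-05, and adjusted p = 0.0483 with an estimated correlation). Cd36, a fatty acid receptor, rose by 2.90 ± 0.24 and Slc27a1, a fatty acid transporter, by 2.94 ± 0.26. Of 4 adipocyte markers tested, 1 rose, Fabp4 (1.73 ± 0.50, adjusted p = 0.0119), also a member of the lipid list, with the same count adjusted over the list alone. The adipocyte marker mean was 3.30 in DEHP 6 against 2.15 to 2.57 in the other DEHP libraries. Mogat1, a monoacylglycerol acyltransferase (gene 68393, chromosome 1, 78511060 to 78606964), rose from 0.19 ± 0.23 to 17.1 ± 3.46 FPKM (6.37 ± 0.38).

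Genes of cholesterol synthesis also rose, 21 of 24 with none falling (22 adjusted over the list alone; camera adjusted p = 3.45e-16, and adjusted p = 0.112 with an estimated correlation). Fdft1, squalene synthase (gene 14137, chromosome 14, 63145150 to 63181687), rose from 39.5 ± 9.41 to 105 ± 18.5 FPKM (1.39 ± 0.16, adjusted p = 4.38e-07), and Cyp51 by 1.15 ± 0.13. In fatty acid and triglyceride synthesis 12 of 23 genes rose and 5 fell (14 and 5 adjusted over the list alone; camera adjusted p = 0.00802, and adjusted p = 0.48 with an estimated correlation). Me1, which supplies NADPH, rose by 1.48 ± 0.17, while Pklr, liver pyruvate kinase (-1.54 ± 0.15), and Lpin1 (-1.37 ± 0.20) fell. Of 29 genes of the NRF2 and glutathione list, 18 rose and 2 fell (19 and 3 adjusted over the list alone; camera adjusted p = 1.3e-05, and adjusted p = 0.219 with an estimated correlation). Gpx4, a lipid peroxide reductase, rose by 0.76, and Gstp1, a glutathione transferase, changed by -1.27 ± 0.17. Of 14 ethanol and aldehyde metabolism genes, 8 rose and none fell (10 and 1 adjusted over the list alone; camera adjusted p = 9.84e-06, and adjusted p = 0.201 with an estimated correlation). The fatty aldehyde dehydrogenase gene Aldh3a2 (1.85 ± 0.17), Adh1 (0.60 ± 0.13) and Cyp2e1 (0.49 ± 0.12) were among them.

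Cyp2b10, the usual marker of the receptor CAR (gene 13088, chromosome 7, 25897658 to 25926624), rose from 2.98 ± 1.81 to 24.7 ± 10.2 FPKM (3.03 ± 0.43, adjusted p = 1.02e-05), with reads that may be shared with its paralog Cyp2b9 (6.98 ± 0.76). Cyp3a11, the usual marker of PXR, was not called (0.19, adjusted p = 0.263). Of 25 genes of the CAR and PXR list, 10 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.0379, and adjusted p = 0.498 with an estimated correlation). The median member moved by 0.02, a value below 0 under several other settings, and the list did not pass without vehicle 1 or any of DEHP 2, 3 or 6 (adjusted p 0.0515 to 0.221).

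The proteasome list rose in 25 of 31 members, with the same count adjusted over the list alone (camera adjusted p = 7.04e-10, and adjusted p = 0.201 with an estimated correlation), with the catalytic subunit gene Psmb5 at 0.65 ± 0.11. The OXPHOS list rose in 20 of 37 members (27 adjusted over the list alone; camera adjusted p = 7.01e-08, and adjusted p = 0.27 with an estimated correlation). After removal of the trend with gene length, the proteasome median was 0.22 in place of 0.34 with 19 members risen, and the OXPHOS median 0.10 in place of 0.23 with 8. Ribosomal protein genes rose in 5 of 37 (1 adjusted over the list alone; camera adjusted p = 0.00874, and adjusted p = 0.747 with an estimated correlation). That call was lost without vehicle replicate 3 (adjusted p = 0.0607). After removal of the length trend the median was 0.02 in place of 0.14, and camera pointed downward with no call. Of 16 cell cycle genes, 9 rose and none fell (10 adjusted over the list alone; camera adjusted p = 0.000156, and adjusted p = 0.201 with an estimated correlation). Mcm6, a replication helicase subunit, rose by 1.96 ± 0.25 and Cdc20, an activator of the anaphase-promoting complex, by 3.19 ± 0.53. With only genes at 5 FPKM or more in 6 samples, the median of the cell cycle list was 0.39 in place of 0.74 and it did not pass.

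The complement, secreted protein, periportal and male-biased lists were shifted downward and the female-biased list upward. Of 29 complement and coagulation genes, 19 fell and none rose (20 adjusted over the list alone; camera adjusted p = 5.76e-09, and adjusted p = 0.0655 with an estimated correlation), with C8a at -1.02 ± 0.15 and C1s1 at -0.84 ± 0.09. Of 18 secreted protein genes, 11 fell (12 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.81e-05, and adjusted p = 0.229 with an estimated correlation), including albumin, Alb (-0.64 ± 0.11). Of 15 periportal genes, 8 fell (8 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.000309, and adjusted p = 0.229 with an estimated correlation). Of 21 male-biased genes, 9 fell and 2 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.000359, and adjusted p = 0.48 with an estimated correlation). The male-biased members that rose were Cyp4a12a (1.72 ± 0.14) and Cyp4a12b (2.42 ± 0.16), close paralogs that may share reads. Of 22 female-biased genes listed, 8 were tested, of which 5 rose and none fell, with the same count adjusted over the list alone (camera adjusted p = 0.00053, and adjusted p = 0.0372 with an estimated correlation). The filter can let in genes low in vehicle because they are higher in another group, so the share that rose may be raised by it. The female-biased members include Cyp2a4, a steroid hydroxylase (gene 13086, chromosome 7, 26307192 to 26315088; 6.00 ± 0.55) whose reads may be shared with the near-identical Cyp2a5, but also the peroxisome proliferator targets Cyp4a14 and Acot3 (3.16 ± 0.50). Ghr, the growth hormone receptor, fell by 0.43 ± 0.07 and Igf1, its main target, by 0.58 ± 0.11 on the log2 scale, whereas Igfbp2, an IGF binding protein, rose by 1.04 ± 0.17. Their list did not pass (1 rose and 3 fell of 12; 2 and 5 adjusted over the list alone; camera adjusted p = 0.161). Hamp, which encodes the iron hormone hepcidin (gene 84506, chromosome 7, 30942368 to 30944029), fell from 1302 ± 459 to 357 ± 179 FPKM (-1.91 ± 0.32, adjusted p = 8.96e-05).

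**Figure D3:**
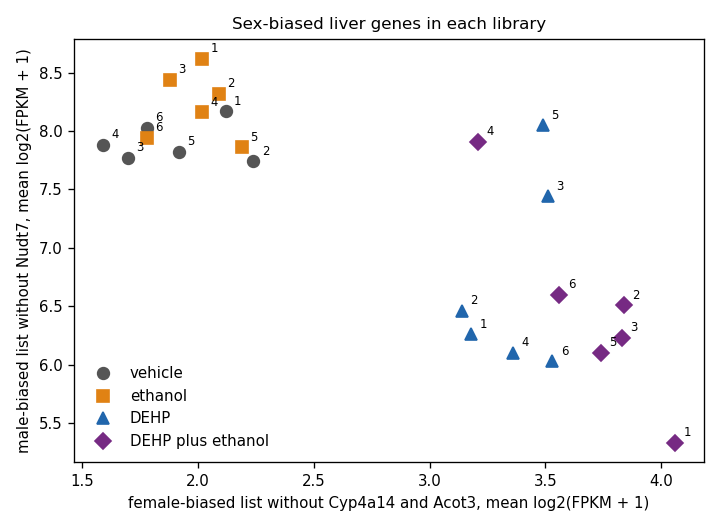
Mean log2(FPKM + 1) of the female-biased list without Cyp4a14 and Acot3 (x axis) against the male-biased list without Nudt7 (y axis) in each library, with colours and shapes for the 4 groups and numbers for replicates. The female-biased mean was 1.59 to 2.24 without DEHP and 3.14 to 4.06 with it, whereas DEHP replicates 3 and 5 and combination replicate 4 had male-biased means of 7.44, 8.05 and 7.91, above 6.60, the highest of the other 9 libraries with DEHP.

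Smaller calls rested on fewer libraries. The acute phase list (1 of 25 rose and 8 fell; 1 and 10 adjusted over the list alone; camera adjusted p = 0.0297, and adjusted p = 0.747 with an estimated correlation) was lost without vehicle 1 or 2 or DEHP 2 or 4 (adjusted p 0.0557 to 0.281). The interferon list (5 of 20 fell, also adjusted over the list alone; camera adjusted p = 0.0365, and adjusted p = 0.656 with an estimated correlation) was lost without vehicle 1, 2 or 3 or DEHP 4 (adjusted p 0.053 to 0.169). The clock list (1 of 16 rose and 7 fell, also adjusted over the list alone; camera adjusted p = 0.0336, and adjusted p = 0.112 with an estimated correlation) was lost without vehicle 4 or DEHP 3 (adjusted p 0.0526 to 0.0542). In that list Nr1d1 rose by 1.5 ± 0.33, and the clock repressor Per1 changed by -1.66 ± 0.31. In all, 2778 genes passed, 1537 higher and 1241 lower, and 20 of 37 lists passed camera, 13 upward and 7 downward, 4 of them with an estimated correlation. Among the 117 named genes that passed, 114 lay beyond the vehicle mean in all 6 DEHP libraries, and Crp, Nr1d1 and Jak2 did so in 5 of 6. For 86 the groups did not overlap, a description of genes chosen because they were called and not a test. Of the 17 fixed genes tested, 11 rose, none fell and 6 were not called.

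DEHP plus ethanol against vehicle. The combination raised the same oxidation lists. Cyp4a14 reached 4150 ± 844 FPKM (4.99 ± 0.43, adjusted p = 3.54e-09) and Ehhadh 2659 ± 782 FPKM (4.76 ± 0.24, adjusted p = 2.41e-13), with n = 6 per group. Cyp2a4 rose from 0.29 ± 0.23 to 50.5 ± 24.6 FPKM (7.42 ± 0.53), Rad51b, a recombination gene, from 0.48 ± 0.56 to 19.3 ± 4.23 FPKM (5.25 ± 0.41), and Serpina12 fell by 6.09 ± 0.49 on the log2 scale. Peroxisomal and omega oxidation had 22 members higher and 1 lower of 25 (23 and 1 adjusted over the list alone; camera adjusted p = 1.81e-17, and adjusted p = 0.041 with an estimated correlation). Mitochondrial oxidation had 22 higher and 1 lower of 27, with the same counts adjusted over the list alone (camera adjusted p = 2.69e-19, and adjusted p = 0.041 with an estimated correlation). Lipid uptake and droplets had 16 higher and 4 lower of 25 (17 and 5 adjusted over the list alone; camera adjusted p = 1.12e-05, and adjusted p = 0.041 with an estimated correlation). Fabp1, the liver fatty acid binding protein, rose by 1.42 ± 0.12 and Cidea, a lipid droplet protein, by 3.21 ± 0.70. Cidea and Fabp4 are also adipocyte markers, of which 2 rose and 1 fell of 4 tested, with the same counts adjusted over the list alone. Fabp4 was at 1.34 ± 0.50 (adjusted p = 0.0374), a call lost without any of vehicle 2 to 6 or combination 1, 5 or 6 (adjusted p 0.0517 to 0.0791), and at 1.97 without vehicle 1. Cidea was at 4.02 without vehicle 1. The adipocyte marker mean was 3.78 in combination 6 against 1.97 to 2.32 in the other combination libraries, and without the 3 libraries that held other tissues the lipid list still passed (camera adjusted p = 8.06e-07).

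Cholesterol synthesis rose in 23 of 24 members, with the same count adjusted over the list alone (camera adjusted p = 8.89e-16, and adjusted p = 0.12 with an estimated correlation), with Fdft1 at 1.53 ± 0.16. Fatty acid and triglyceride synthesis rose in 14 of 23 with 3 lower (16 and 5 adjusted over the list alone; camera adjusted p = 0.00109, and adjusted p = 0.311 with an estimated correlation). Fasn, fatty acid synthase, rose by 1.23 ± 0.29. The proteasome list rose in 29 of 31 members, with the same count adjusted over the list alone (camera adjusted p = 2.2e-15, and adjusted p = 0.111 with an estimated correlation). OXPHOS subunits rose in 31 of 37 (32 adjusted over the list alone; camera adjusted p = 7.76e-12, and adjusted p = 0.204 with an estimated correlation). Ribosomal protein genes rose in 26 of 37 (30 adjusted over the list alone; camera adjusted p = 1.77e-07, and adjusted p = 0.311 with an estimated correlation), and their median fell from 0.29 to 0.05, with no call, once the length trend was removed. With the same removal the proteasome median went from 0.50 to 0.32 with 25 members risen, and the OXPHOS median from 0.39 to 0.15 with 13. The NRF2 and glutathione list had 18 higher and 3 lower of 29 (20 and 3 adjusted over the list alone; camera adjusted p = 8.01e-06, and adjusted p = 0.204 with an estimated correlation). Ethanol and aldehyde metabolism had 8 higher and 1 lower of 14 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00109, and adjusted p = 0.311 with an estimated correlation).

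Complement and coagulation fell in 20 of 29 members (21 adjusted over the list alone; camera adjusted p = 2.33e-09, and adjusted p = 0.0581 with an estimated correlation), with the terminal component C9 at -1.71 ± 0.21. Secreted proteins fell in 12 of 18 with 1 higher, also adjusted over the list alone (camera adjusted p = 0.000124, and adjusted p = 0.277 with an estimated correlation). Periportal genes fell in 9 of 15, also adjusted over the list alone (camera adjusted p = 9.85e-05, and adjusted p = 0.204 with an estimated correlation). Urea cycle and amino acid genes fell in 12 of 25 with 1 higher (13 and 1 adjusted over the list alone; camera adjusted p = 0.00481, and adjusted p = 0.482 with an estimated correlation), including Cps1, the entry enzyme of the urea cycle (-0.71 ± 0.11). Gluconeogenesis and fasting genes fell in 7 of 16 with 2 higher (9 and 2 adjusted over the list alone; camera adjusted p = 0.00839, and adjusted p = 0.261 with an estimated correlation), with G6pc at -1.26. Male-biased genes fell in 11 of 21 with 2 higher (14 and 2 adjusted over the list alone; camera adjusted p = 0.000303, and adjusted p = 0.442 with an estimated correlation). Female-biased genes rose in 5 of the 8 tested, out of 22 listed, also adjusted over the list alone (camera adjusted p = 0.00109, and adjusted p = 0.041 with an estimated correlation). Hsd3b5, a male-biased steroid dehydrogenase, fell by 2.58 on the log2 scale, and by 4.73 without combination replicate 4. Acute phase genes fell in 15 of 25 with 2 higher, also adjusted over the list alone (camera adjusted p = 0.0118, and adjusted p = 0.588 with an estimated correlation). This call was lost without vehicle 1 or 2 (adjusted p 0.0762 to 0.108). Interferon genes fell in 6 of 20 with 1 higher, also adjusted over the list alone (camera adjusted p = 0.0191, and adjusted p = 0.537 with an estimated correlation). It was lost without vehicle 2 or 3 or combination 1 (adjusted p 0.0548 to 0.083). In all, 3932 genes passed, 2067 higher and 1865 lower, while limma on TPM gave 1764 and 1877 and on quantile-normalised values 1764 and 1798. Of the 37 lists, 19 passed, 11 upward and 8 downward, 4 with an estimated correlation. Among the 133 named genes that passed, 130 lay beyond the vehicle mean in all 6 libraries, and Mup1, Manf and Mdm2 did so in 5 of 6. For 103, again among genes chosen because they were called, the groups did not overlap.

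DEHP plus ethanol against DEHP. Adding ethanol to DEHP changed few genes. Gadd45g, a stress-induced growth arrest gene (gene 23882, chromosome 13, 51846675 to 51848475), was higher at 16.7 ± 7.51 than at 3.32 ± 0.77 FPKM (n = 6 per group; 2.32 ± 0.48, adjusted p = 0.0421). Slc25a25, a mitochondrial ATP-Mg carrier, was higher at 32.8 ± 9.68 than at 14.4 ± 6.43 FPKM (1.21 ± 0.24, adjusted p = 0.0318). Trp53inp1 (gene 60599, chromosome 4, 11156441 to 11174379) was lower at 9.28 ± 0.76 than at 15.5 ± 2.48 FPKM (-0.72 ± 0.12, adjusted p = 0.0236). Ppp1r10, a regulatory subunit of a protein phosphatase (-1.32 ± 0.28, adjusted p = 0.0499), and Cpeb2, a translational regulator (-0.70 ± 0.13, adjusted p = 0.0318), were lower as well. In all, 13 genes passed, 5 higher and 8 lower, while 1159 had an unadjusted p below 0.05, and DESeq2 called 44. All 11 named genes lay beyond the DEHP mean in all 6 combination libraries, and for 10 the groups did not overlap. Since the genes were named because they were called, this separation adds no support to the calls. No gene passed in edgeR without combination 1, 2 or 5 or without DEHP 2 or 3, with 873, 1006, 1090, 956 and 916 genes at an unadjusted p below 0.05, and 6, 6 and 4 genes passed without combination 3, DEHP 5 and DEHP 6. TPM gave 2 higher and 8 lower, median-ratio scaling of FPKM 4 and 4, quantile normalisation 1 and 4, and removal of the length trend 1 and 1.

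Cyp4a14 (0.40 ± 0.37, adjusted p = 0.72) and Cyp7a1 (-0.97 ± 0.35, adjusted p = 0.326) were not called, nor was any other of the 17 fixed genes. Lists nevertheless shifted by small amounts, with 17 of 37 passing camera, 10 upward and 7 downward, and 0 with an estimated correlation. The proteasome list had a median of 0.19 (camera adjusted p = 9.59e-13, and adjusted p = 0.246 with an estimated correlation), with 0 of 31 members called and 4 higher adjusted over the list alone. The mitochondrial oxidation list had a median of 0.15 (camera adjusted p = 0.000104, and adjusted p = 0.436 with an estimated correlation), with 0 of 27 members called, and 0 adjusted over the list alone. The peroxisomal and omega oxidation list had a median of 0.14 (camera adjusted p = 0.0226, and adjusted p = 0.574 with an estimated correlation), with 0 of 25 called in both ways, and did not pass without combination 1 or 3 or DEHP 5 (adjusted p 0.0946 to 0.393). Ribosomal protein genes (camera adjusted p = 1.05e-10), OXPHOS subunits (camera adjusted p = 5.24e-08) and endoplasmic reticulum stress genes (camera adjusted p = 8.47e-06) were also shifted upward, each at an adjusted p = 0.34 with an estimated correlation. In each of these 3 lists 0 members were called, and 0 adjusted over the list alone. The OXPHOS list had a median of 0.11, and of 0.03 with no call once the length trend was removed. The ribosomal and proteasome lists still passed after that removal. The cell cycle list was shifted downward with a median of -0.45 (camera adjusted p = 1.15e-06, and adjusted p = 0.184 with an estimated correlation), with 0 of 16 members called and 4 lower adjusted over the list alone. Of 12 p53 targets, 1 was lower (3 adjusted over the list alone; camera adjusted p = 0.00113, and adjusted p = 0.153 with an estimated correlation). Heat shock genes were shifted upward (0 of 14 called, 3 adjusted over the list alone; camera adjusted p = 0.0019, and adjusted p = 0.34 with an estimated correlation).

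DEHP plus ethanol against ethanol. With ethanol in both groups, DEHP again raised most genes of fatty acid oxidation. Cyp4a14 rose by 4.78 ± 0.43 (adjusted p = 6.77e-09), Ehhadh by 4.65 ± 0.24 (adjusted p = 5.59e-13), Cd36 by 3.63 ± 0.25 and Mogat1 by 5.52 ± 0.34 (n = 6 per group). Cdkn1a was higher at 23.1 ± 3.39 than at 1.5 ± 0.46 FPKM (3.85 ± 0.21, adjusted p = 1.31e-12), and Dbp was lower at 2.44 ± 2.20 than at 48.2 ± 25.7 FPKM (-4.22 ± 0.38, adjusted p = 6.77e-09). Cyp7a1 was lower by -1.42 ± 0.35 (adjusted p = 0.00359). Mitochondrial oxidation had 23 members higher and 1 lower of 27 (24 and 1 adjusted over the list alone; camera adjusted p = 5.69e-18, and adjusted p = 0.0424 with an estimated correlation). Peroxisomal and omega oxidation had 20 higher and 1 lower of 25 (21 and 1 adjusted over the list alone; camera adjusted p = 1.05e-16, and adjusted p = 0.0424 with an estimated correlation). Lipid uptake and droplets had 15 higher and 1 lower of 25, also adjusted over the list alone (camera adjusted p = 3.58e-07, and adjusted p = 0.0175 with an estimated correlation). Of 4 adipocyte markers, 3 rose and 1 fell, also adjusted over the list alone, with Fabp4 at 2.75 ± 0.57, Cidea at 4.68 ± 0.89 and Cfd at 5.68 ± 1.63, the last at 3.04 and not called without combination 6. All 31 proteasome genes rose, also adjusted over the list alone (camera adjusted p = 7.31e-13, and adjusted p = 0.1 with an estimated correlation). So did 21 of 24 cholesterol synthesis genes, also adjusted over the list alone (camera adjusted p = 1.35e-14, and adjusted p = 0.1 with an estimated correlation). Pmvk, a mevalonate pathway kinase, rose by 1.67 ± 0.15.

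Heat shock genes rose in 11 of 14 members, also adjusted over the list alone (camera adjusted p = 9.69e-08, and adjusted p = 0.0619 with an estimated correlation), including the mitochondrial chaperonin Hspe1 (1.00 ± 0.09). Of 12 p53 targets, 4 rose (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0096, and adjusted p = 0.0887 with an estimated correlation). The clock list had 3 members higher and 9 lower of 16 (3 and 10 adjusted over the list alone; camera adjusted p = 0.02, and adjusted p = 0.0622 with an estimated correlation). Complement and coagulation genes fell in 22 of 29 (23 adjusted over the list alone; camera adjusted p = 2.82e-15, and adjusted p = 0.0175 with an estimated correlation). Secreted proteins fell in 14 of 18, also adjusted over the list alone (camera adjusted p = 1.05e-10, and adjusted p = 0.0622 with an estimated correlation). Male-biased genes fell in 16 of 21 with 2 higher (17 and 2 adjusted over the list alone; camera adjusted p = 6.79e-08, and adjusted p = 0.242 with an estimated correlation). Pericentral genes fell in 6 of 16, also adjusted over the list alone (camera adjusted p = 0.00726, and adjusted p = 0.394 with an estimated correlation), with Cyp1a2 at -1.06 ± 0.11. Endoplasmic reticulum stress genes rose in 10 of 24, also adjusted over the list alone (camera adjusted p = 0.0367, and adjusted p = 0.584 with an estimated correlation). Hspa5, the chaperone BiP, rose by 1.18 ± 0.20. That list call was lost without combination 3 or 4 or ethanol 4 (adjusted p 0.069 to 0.0869). It was also lost under 10 other settings, the planned limma on log2(FPKM + 1) among them. In all, 2976 genes passed, 1620 higher and 1356 lower, and 20 of 37 lists, 13 upward and 7 downward, 5 with an estimated correlation. On TPM 2563 were higher and 695 lower with a shift of 0.12 in the median of all genes, limma on log2(FPKM + 1) gave 2110 and 942, and edgeR without TMM factors 2198 and 915. Among the 117 named genes that passed, 116 lay beyond the ethanol mean in all 6 combination libraries, and Klf15 did so in 5 of 6. For 105, again among genes chosen because they were called, the groups did not overlap.

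The DEHP by ethanol interaction. The change from DEHP to the combination differed from that from vehicle to ethanol in 686 genes. For Cdkn1a the interaction was 4.65 ± 0.27 (adjusted p = 1.36e-11), with means of 56.3, 1.5, 32.7 and 23.1 FPKM in the vehicle, ethanol, DEHP and combination groups (n = 6 each). For Dbp it was -4.92 ± 0.70 (adjusted p = 0.000131), with means of 0.82, 48.2, 1.35 and 2.44 FPKM. Lpin1 (2.78 ± 0.29, adjusted p = 1.74e-06), Ppard, a nuclear receptor for fatty acids (gene 19015, chromosome 17, 28232754 to 28301469; 2.68 ± 0.31, adjusted p = 1.07e-05), and Npas2 (2.91 ± 0.42, adjusted p = 0.000131) had positive interactions. Cyp7a1 had a negative one (-2.43 ± 0.50, adjusted p = 0.00459), with 13.4 ± 4.75, 35.6 ± 18.2, 27.6 ± 10.1 and 13.9 ± 7.96 FPKM in the same order.

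**Figure D4:**
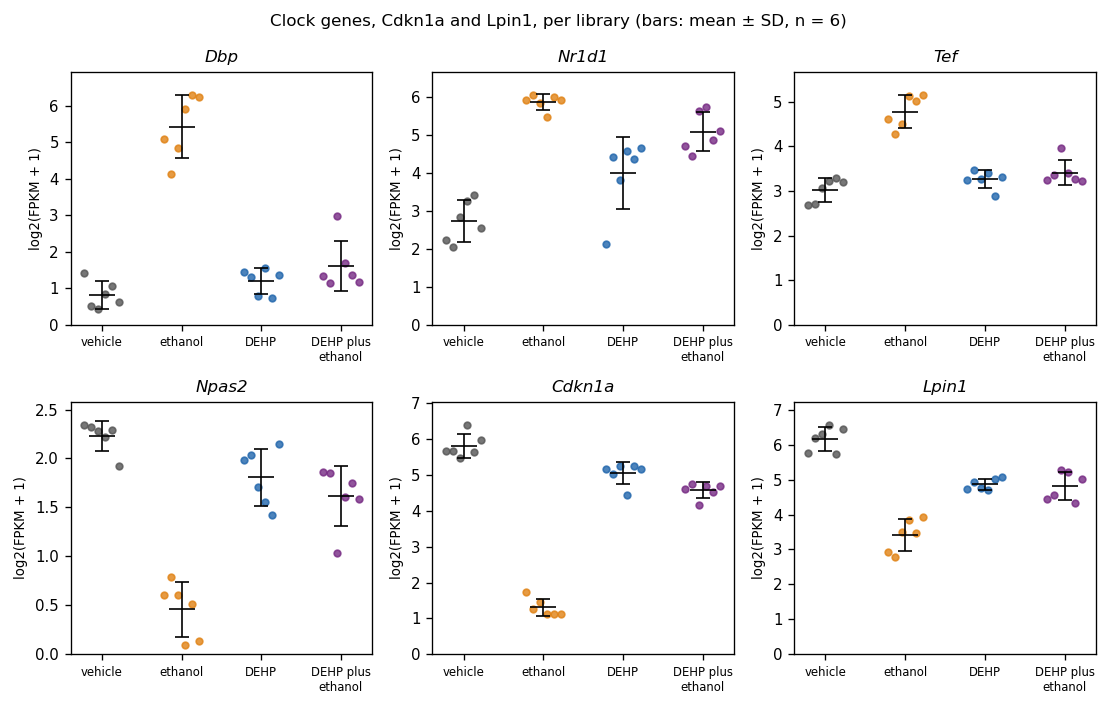
Expression, as log2(FPKM + 1), of Dbp, Nr1d1, Tef, Npas2, Cdkn1a and Lpin1 (y axes) in the 4 groups (x axes), with each point a library and bars showing the mean and SD of 6. Dbp averaged 48.2 FPKM with ethanol and 0.82 to 2.44 FPKM in the other 3 groups, and Cdkn1a 1.5 FPKM with ethanol and 23.1 to 56.3 FPKM in the others.

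Of the 16 clock genes, 5 had a positive and 4 a negative interaction (5 and 6 adjusted over the list alone; camera adjusted p = 0.833, fry mixed test adjusted p = 9.23e-08). They included Nr1d1 (-2.30 ± 0.44, adjusted p = 0.00279), Tef (-1.77 ± 0.24) and Nfil3 (1.06 ± 0.20). Heat shock genes had positive interactions in 7 of 14 (8 adjusted over the list alone; camera adjusted p = 1.44e-07, and adjusted p = 0.269 with an estimated correlation), with Hsph1 at 1.63 ± 0.28 and Hspa1b at 1.29 ± 0.24. Endoplasmic reticulum stress genes were positive in 8 of 24 and negative in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.000563, and adjusted p = 0.817 with an estimated correlation), with Hspa5 at 1.40 ± 0.28 and the secreted stress factor Manf at 1.53. Pericentral genes were negative in 2 of 16 (7 adjusted over the list alone; camera adjusted p = 0.000856, and adjusted p = 0.817 with an estimated correlation), with Cyp1a2 at -0.92 ± 0.16. In gluconeogenesis and fasting, 3 of 16 were positive and 1 negative (4 and 2 adjusted over the list alone; camera adjusted p = 0.278, fry mixed test adjusted p = 2.9e-08), with G6pc at 1.47 ± 0.27 and Igfbp1 at 2.52 ± 0.63. Bile acid genes were negative in 3 of 21 (4 adjusted over the list alone; camera adjusted p = 0.0133, and adjusted p = 0.817 with an estimated correlation). This last call was lost without vehicle replicate 1 (adjusted p = 0.0976).

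Among the oxidation and lipid lists, none of 25 peroxisomal and omega oxidation genes had a called interaction, nor any adjusted over the list alone (camera adjusted p = 0.691, fry mixed test adjusted p = 0.354). Of 27 mitochondrial oxidation genes, 3 had a positive interaction, Pdk4 among them, also adjusted over the list alone (camera adjusted p = 0.903, fry mixed test adjusted p = 0.0887). Of 25 lipid uptake and droplet genes, 5 had a positive and 1 a negative interaction (7 and 2 adjusted over the list alone; camera adjusted p = 0.183, fry mixed test adjusted p = 4.87e-09). The fatty acid and triglyceride synthesis list did pass camera (adjusted p = 0.0474). That call was lost without any of 10 libraries (adjusted p 0.0535 to 0.152) and under 3 other settings. Ehhadh was at 0.03 ± 0.30 (adjusted p = 0.971) and Cyp4a14 at 0.19 ± 0.52 (adjusted p = 0.856). The muscle transcripts Fabp3 (12.78) and Mylpf (11.55) passed only with the libraries that held muscle RNA, and were not called without vehicle 1 (6.76 and 5.10) or combination 6 (8.56 and 5.67). Pdk4 stood at 2.49, and at 1.08 with no call without vehicle 1. In all, 686 genes passed, 355 positive and 331 negative, while DESeq2 called 958, and 10 of 37 lists passed camera, 4 upward and 6 downward, and 0 with an estimated correlation. TPM gave 439 positive and 120 negative with a shift of 0.11 in the median of all genes, quantile normalisation 275 and 392, and edgeR without TMM factors 447 and 203. Without the 3 libraries that held other tissues, 365 genes passed, 346 of them also called with all libraries.

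Comparisons against vehicle shared their 6 control libraries. Ethanol and DEHP raised 505 genes in common and lowered 569, with 96 moved in opposite directions, where independent lists would share 219 and 180. Over genes the correlation of the changes was 0.41 and their covariance 0.097, against 0.50 and 0.0223 in 20 simulations of unchanged groups, which shared no called genes. With the vehicle libraries divided between the comparisons, 300 to 442 genes were shared over 20 divisions and the median correlation was 0.19. DEHP and the combination raised 1334 genes in common and lowered 1017, with none opposite, where independent lists would share 297 and 216. Their correlation was 0.86 and covariance 0.236, against 0.51 and 0.0222 in simulation, and 1165 to 1328 genes were shared with divided controls, at a median correlation of 0.62. Ethanol and the combination raised 693 in common, lowered 832 and moved 116 in opposite directions, where independent lists would share 294 and 271. Their correlation was 0.40 and covariance 0.098, against 0.51 and 0.0222 in simulation, and 510 to 778 genes were shared with divided controls, at a median correlation of 0.21. Between comparisons with no library in common, DEHP without and with ethanol raised 841 genes in common and lowered 425, with 68 opposite, where independent lists would share 233 and 157. Ethanol without and with DEHP raised 2 and lowered 5 in common, where independent lists would share 1 and 1, at a correlation of 0.01.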

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

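All tests weighed here were chosen after the result was seen, except the divisions of the libraries, the pancreas test against the median and the effect of gene length on the clock genes, which were written down first. The pancreas test was written for a library already picked out for pancreatic transcripts.

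Clock genes differed between ethanol and vehicle livers, with interactions of -4.92 for Dbp, -2.30 for Nr1d1 and -1.77 for Tef. A trend with gene length is argued against, since 12 of the 13 called clock genes were still called with the same sign after its removal. An ethanol effect on the clock that is the same with or without DEHP is argued against by the interaction over all 16 tested genes of the list fixed beforehand (fry mixed test adjusted p = 9.23e-08). A difference in the time of day at which livers were collected may also account for the pattern, since 11 of 11 tested genes that peak in opposite phases moved as 1 shift of phase needs, 10 of them called. With no collection time in the labels, collection time and a shift of the clock by the treatment cannot be told apart.

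The ribosomal protein, OXPHOS subunit and proteasome lists were shifted upward against vehicle in all 3 comparisons, although 0 of these 9 calls held with an estimated correlation (adjusted p 0.111 to 0.905). Their transcripts are short (median lengths 740, 999 and 1339 bases, against 2704 over all genes), and the slope of expression on length was 0.084 ± 0.023 (SD, n = 6) in vehicle libraries and -0.020 ± 0.056, -0.007 ± 0.030 and -0.057 ± 0.043 with ethanol, DEHP and the combination. Removing that trend ended all the ribosomal calls against vehicle, with 0 of 3 kept. Their medians went from 0.23, 0.14 and 0.29 (interquartile ranges 0.162, 0.132 and 0.14) to 0.10, 0.02 and 0.05 (0.16, 0.133 and 0.118). These calls thus ended because the medians shrank and not because the spread grew. The ribosomal call for the combination against DEHP was kept after the same removal. For OXPHOS subunits and the proteasome, 0 of 2 calls with ethanol alone were kept, where medians of 0.15 and 0.15 (0.212 and 0.229) became 0.03 and 0.02 (0.221 and 0.193), but 4 of 4 with DEHP or the combination still passed, at smaller medians (OXPHOS from 0.23 and 0.39 to 0.10 and 0.15, proteasome from 0.34 and 0.50 to 0.22 and 0.32), which argues against length as the whole cause there but not as a part of it. Mean total counts were 7580799 with vehicle and 7813995, 7619032 and 7818396 with ethanol, DEHP and the combination; no valid test of whether depth moved these lists was made, and a response of short transcripts to treatment stays open.

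Single libraries held transcripts of another tissue. Among genes that did not enter the tests, Acta1 was at 1775 FPKM in vehicle 1 and 1460 in DEHP plus ethanol 6 (at most 0.91 elsewhere), and Ctrb1 and Amy2a5 at 162.2 and 128.1 FPKM in DEHP 6 (at most 0.19 elsewhere). Skeletal muscle collected with the liver may explain the first pair, since 8 of 8 abundant muscle transcripts outside the fixed list, such as Tnnt3 (1206 and 893 FPKM, against a median of 0.29) and Mb (487 and 426 FPKM), were over 10 times the median of the other libraries in both. Pancreas may explain DEHP 6, since 8 of 8 acinar transcripts outside the list passed the same bar, a low one where the median elsewhere was 0, as for 7 of them, and 8 of 8 were higher than in any of the other 23 libraries, among them Sycn (16.4 FPKM) and Reg1 (14.2 FPKM). The labels describe liver alone, and no biological explanation was tested.

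The following values stand apart from the other 5 libraries of their group by a gap test that chance passes in about 1 of 20 groups, and 116 groups were tested for single measures. The muscle list had a mean log2(FPKM + 1) of 6.94 in vehicle 1 (others 0.247 to 0.512), 6.59 in DEHP plus ethanol 6 (0.0976 to 0.203) and 0.314 in ethanol 1 (0.056 to 0.137), and the acinar list 5.40 in DEHP 6 (0.373 to 0.42). The adipocyte list was at 3 in vehicle 1 (1.69 to 1.98), 3.30 in DEHP 6 (2.15 to 2.57) and 3.78 in DEHP plus ethanol 6 (1.97 to 2.32), and the stellate cell list at 3.15 in vehicle 1 (2 to 2.31). In DEHP 1 the macrophage list was at 4.24 (3.06 to 3.28) and the neutrophil list at 2.05 (0.284 to 0.589). Vehicle 1 listed 15114 genes (14231 to 14401) and DEHP plus ethanol 6 listed 14902 (14062 to 14312).

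Among fixed genes, Pdk4 was at 34.7 FPKM in vehicle 1 (2.28 to 3.74). In DEHP plus ethanol 4, Cyp2b10 was at 6.42 FPKM (24.6 to 31.9) and Srebf1 at 55.4 (79.4 to 86.9). In ethanol 4, Scd1 was at 1919 FPKM (1047 to 1267) and Cpt1a at 108 (73.0 to 82.3), and Cat was at 1166 FPKM in DEHP 1 (1330 to 1397). Over 273 named genes, the number in which a library stood apart was 15, 2, 5, 0, 2 and 3 for vehicle 1 to 6, and 3, 1, 3, 8, 3 and 2 for ethanol 1 to 6. It was 10, 2, 0, 4, 6 and 1 for DEHP 1 to 6, and 1, 0, 7, 14, 2 and 5 for DEHP plus ethanol 1 to 6.

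By the interaction test, the change from DEHP to the combination differed from that from vehicle to ethanol in 686 genes. With no collection time in the labels, treatment and time of collection cannot be told apart for these genes either. Named interactions on the log2 scale included 4.65 for Cdkn1a, 2.91 for Npas2, 2.78 for Lpin1, 2.68 for Ppard, 2.52 for Igfbp1, 2.50 for Gadd45g, 3.72 for Chrna4 and 2.49 for Pdk4. Those of the muscle transcripts Fabp3 and Mylpf were 12.78 and 11.55. Negative interactions were found for Cyp7a1 (-2.43), Arrdc3 (-2.13), Clec2h (-2.34), Cdc20 (-3.60) and Rnf8-cmtr1 (-2.55), a read-through gene that shares sequence with its neighbours.

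Whether chance could give as many calls was tested over 100 divisions of the same libraries into groups of the same sizes, the real one included. For ethanol against vehicle 1 division, the real one, gave as many as 3079, with 1194 in the highest of the others. The real division was also the only 1 for DEHP against vehicle (2778, highest other 1455), the combination against vehicle (3932, highest other 1751) and the combination against ethanol (2976, highest other 1003). Chance can be excluded for these at the limit of 5 in 100. For the interaction (686, highest other 100) the real division was the only 1 as well. Its other divisions mixed vehicle with ethanol libraries and DEHP with combination libraries, which also broke up any ethanol effect common to both. They therefore cannot exclude chance for the interaction by itself. For the combination against DEHP 3 divisions gave at least 13, a share below the limit of 5 in 100 set for excluding chance. That exclusion is weak, since 1 of the others called 283, many times the real count, which points to a structure among these 12 libraries whose nature was not tested, and since no gene passed without any 1 of 5 libraries.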

How the results depend on the processing

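DESeq2, removal of the length trend and omission of the 3 libraries with other tissue were chosen after the data were seen, and limma on log2(FPKM + 1), the planned test, became an alternative then. Over 20 other settings and 24 single omissions, counts were within 1.5 times the main count in 99 of 122 and 136 of 144 values. For 580 results on named genes, 10577 of 10920 values under other settings kept direction and side of the threshold, 305 lost the call, 34 gained it and 4 reversed. With single libraries left out it was 13645 of 13920, with 259 lost, 15 gained and 1 reversed. For 222 results on lists, 3979 of 4157 and 5164 of 5328 values kept both. With an estimated correlation 82 results lost the call, which were most of those that had one. The number of lists passing went from 9, 20, 19, 17, 20 and 10 to 0, 4, 4, 0, 5 and 0. The order is ethanol, DEHP and the combination against vehicle, the combination against DEHP and against ethanol, and the interaction. Depth limits the low genes, such as Fgf21, with a mean of 0.86 FPKM in vehicle and 0.25 in the combination, which was not tested.

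Requiring a 2-fold change left 305, 343, 450 and 424 genes for ethanol, DEHP and the combination against vehicle and the combination against ethanol, 5 for the combination against DEHP and 176 for the interaction, fewer by construction. For the combination against DEHP (13 genes), the count was 1 with no filter, 6 with a pseudocount of 0.1 or of 5, 8 with median-ratio scaling in limma, 5 under quantile normalisation, 6 without trend and 5 with robust moderation in limma. It was 6 with only the groups compared, 7 in limma on log2(FPKM + 1), 44 in DESeq2, 8 without the 3 libraries and 2 after removal of the length trend; the cause was not tested. Leaving out single libraries gave 0 to 18. Without the 3 libraries the interaction fell to 365 genes, with fewer samples. With the vehicle libraries split into groups of 3, the overlaps were 344 for ethanol and DEHP, 626 for ethanol and the combination and 1242 for DEHP and the combination.

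Replicate numbers did not pair the samples, since correlations between same-numbered libraries lay between -0.21 and 0.21. The replicate block gave 2930, 2656, 3865 and 2871 genes for ethanol, DEHP and the combination against vehicle and the combination against ethanol, 5 for the combination against DEHP and 599 for the interaction.

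Single values reversed as follows, and the cause was not tested. Under quantile normalisation Ahsg was at -0.095 for ethanol against vehicle and Cyp2e1 at 0.504 for the combination against ethanol. For DEHP against vehicle Pdk4, at -0.019 and not called with all libraries, was at 1.32 without the 3 libraries and at 1.38 without vehicle 1. Its range over single omissions went from -0.21, without vehicle 6 and with no reversal, to that 1.38. The interaction of Mylpf was -0.59 without the 3 libraries.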

Other observations

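Both correlation tests reported here were chosen after the result was seen.

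With ethanol, 5 of 15 metallothionein and iron genes rose and 3 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.885). Slc40a1, the iron exporter ferroportin, rose by 0.82 ± 0.13 and Tfrc, the transferrin receptor, fell by 1.53 ± 0.30 on the log2 scale. Zbtb16, a zinc finger transcription factor (-3.26 ± 0.34, adjusted p = 1.87e-07), Tsc22d3, a leucine zipper protein (-2.08 ± 0.24, adjusted p = 9.95e-07), and Il1r1, the interleukin-1 receptor (-1.43 ± 0.16), were lower after ethanol. Of 12 growth hormone and IGF genes, 2 rose and 3 fell, also adjusted over the list alone, with Igfals, which stabilises circulating IGF, at 0.77 ± 0.11 and the list not passing (camera adjusted p = 0.671).

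The antigen presentation list of 10 genes did not pass camera with ethanol (adjusted p = 0.957) or with DEHP (adjusted p = 0.869). Of 15 macrophage markers, 1 fell with ethanol, which was not called adjusted over the list alone, and the list did not pass with ethanol or with DEHP (camera adjusted p = 0.509 and 0.424).

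Male-biased genes varied between the 12 libraries with DEHP. List means of DEHP 5 (8.05), DEHP plus ethanol 4 (7.91) and DEHP 3 (7.44) lay above a gap of 0.84, and the remaining 9 at or below 6.60, while vehicle libraries lay between 7.74 and 8.17 and ethanol libraries between 7.86 and 8.62. These means leave out Nudt7, and those of the female-biased list leave out Cyp4a14 and Acot3. Both relations below were computed over the 12 libraries, within each group and over the 9 lower libraries, with p adjusted over the 2 relations. A hypothesis is that male-biased genes may be lower where the peroxisomal and omega oxidation list is higher. Over the 12 libraries Pearson's r was -0.81 (permutation p = 0.00069, adjusted 0.0014) and Spearman's rho -0.66 (permutation p = 0.022). Without the 2 libraries farthest from the median of the peroxisomal list r was -0.59, so that the relation rests in part on those libraries. Within DEHP r was -0.80 (exact permutation p = 0.057, adjusted 0.11), rho -0.49 (exact permutation p = 0.36) and r -0.31 without the 2 farthest. Within the combination r was -0.86 (exact permutation p = 0.012, adjusted 0.012), rho -0.83 (exact permutation p = 0.058) and r -0.64 without the 2 farthest. Over the 9 lower libraries, a set chosen by the male-biased mean itself, r was -0.59 (exact permutation p = 0.087, adjusted 0.17), rho -0.40 (exact permutation p = 0.29) and r -0.35 without the 2 farthest. A second is that female-biased and male-biased genes share a control, for which r was -0.44 over the 12 libraries (permutation p = 0.15, adjusted 0.15), rho -0.36 (permutation p = 0.26) and r -0.32 without the 2 farthest. Within DEHP that r was 0.42 (exact permutation p = 0.40, adjusted 0.40), rho -0.14 (exact permutation p = 0.80) and r 0.34 without the 2 farthest. Within the combination r was -0.95 (exact permutation p = 0.011, adjusted 0.012), rho -0.77 (exact permutation p = 0.10) and r -0.43 without the 2 farthest. Over the 9 lower libraries r was -0.49 (exact permutation p = 0.18, adjusted 0.18), rho -0.20 (exact permutation p = 0.61) and r 0.23 without the 2 farthest. The correlations within the combination thus rest in part on the 2 farthest libraries. Both hypotheses stay open.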
